A study of Mus musculus with 6 samples.

How the data were processed

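RNA was measured by sequencing in pachytene spermatocytes, the male germ cells in the long recombination stage of the first meiotic prophase. Per the labels' protocols, the cells came from mice 10 to 25 weeks old that carried a floxed and a null copy of Ythdc2, with or without the tamoxifen-inducible germ-line recombinase Ddx4-CreERT2. The groups thus differ in the recombinase as well as in Ythdc2, and its own effects cannot be told from those of the deletion. Tamoxifen was injected on 5 days at 2 mg per 30 g of body weight, and the cells were purified 2 days after treatment by Staput, which is sedimentation at unit gravity. Libraries were made from 3 µg of total RNA with an Illumina TruSeq kit, per the labels' protocols. The series describes 3 biological replicates for each genotype, giving 6 libraries: 3 heterozygous and 3 inducible knockout (iKO). The labels do not tie any library to a litter, a day or a batch.

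The deposited table gives each gene's normalized count in every library, a signal that the authors had already scaled between samples. The submitters' processing notes name Salmon 1.3.0, DESeq2 1.25.10 and the mouse build GRCm38. Whether the counting used strand is not given in the sources used here. The deposited normalized counts are not whole numbers and whole reads could not be recovered from them, so the sequencing depth is unknown and the column sums are not depths. The table holds protein-coding genes that the authors kept as expressed, 13754 of them, and the smallest mean over libraries is 50. It also holds the authors' own log2 fold change and adjusted p-value for each gene. Both further deposited tables list the genes the authors placed among the higher and the lower ones. Gene identifiers carried symbols in the deposited table, and 13743 of those tested matched GENCODE release M21 on GRCm38 without the version suffix (13208 with it), which gave coordinates, transcript length and GC content.

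Genes with a normalized count of at least 10 in at least 3 libraries were tested, which removed 4 genes and left 13750. The unit does not allow a count model, so the test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) on log2(normalized count + 1), iKO against heterozygous, with no other term. The gene tests were two-sided, and p-values were adjusted by Benjamini-Hochberg, with 0.05 as the threshold. Fold changes are on this log2 scale, where the pseudocount of 1 understates the change of low genes. Group values are means ± SD of the normalized counts over 3 libraries, and the SE of a gene is limma's standard error of its log2 fold change. The SE of a difference between list medians comes from 2000 bootstrap draws of the lists' genes (500 for the X-linked genes and their matches), and it does not hold the spread between libraries. The SE over libraries comes from the variance, within each group, of the gap between the mean log2 levels of both lists. All adjusted p-values for genes come from limma over the genes tested unless they are said to be adjusted over the list alone.

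A total of 28 gene lists (processes and cell types) and the X-linked and Y-linked genes were tested with limma's camera, which compares a list with all other genes, using the preset correlation of 0.01 between genes and then an estimated correlation. These p-values were adjusted over the 30 lists. With the preset correlation 10 lists passed, and with an estimated correlation 0 passed after adjustment and 1, the immediate early genes, was under 0.05 before it. Limma's fry, which tests a list without comparing it with other genes, was run beside camera, and its calls differed. The Leydig list, which passed camera, had a fry adjusted p of 0.122. The tubulin (fry adjusted p = 0.00583), DNA damage (0.00772), interferon (0.0238), heat shock (0.0483) and spermatogonial (0.0483) lists passed fry but not camera.

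The genes named were fixed by a rule before the data were examined. It took Ythdc2, Meioc, Rbm46, Xrn1 and Ccna2 in any case. It added the 10 largest increases and the 10 largest decreases among genes past the threshold, above the median level and without overlap between groups. In each list it took up to 4 members with the smallest p, and in cell type lists also the 2 most abundant. Genes named outside this rule are said to have been chosen after their values were seen.

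The test was tried on simulated data drawn from the means and spreads of the 13750 genes, with 200 genes changed in each of 10 runs. It called 40.6% of genes changed by 1 on the log2 scale and 79.7% of those changed by 2. The mean share of false calls was 4.64%. A raised list was found in 10 of 10 runs and an unchanged list in 0. The simulated genes were drawn independently of each other, while the Sertoli list had an estimated correlation of 0.885 between genes. These runs therefore do not measure the error rates for correlated genes. Far fewer genes were changed in them than were called in the data (38.3% of those tested). The adjusted threshold was thus harder to pass, and the detection rates do not carry over to the data.

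The alternatives were the replicate number as a block, TMM and quantile scaling, no filter and a stricter filter, pseudocounts of 0.1 and 5, limma without trend and with array weights, and each library left out in turn. Tests that need counts were listed for the case that counts were deposited and were not run. After the data were seen, the Sertoli or Leydig marker level was added as a covariate, X-linked genes were left out, and each list's median was set among 10000 random lists of the same size matched in 50 bins of mean level (1000 for the X-linked list and for gene families). An additional list of X-linked genes restricted to germ cells was used without 1 symbol that lies on an autosome. Figures were drawn with matplotlib 3.10.9.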

Results

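Ythdc2 encodes a meiotic RNA helicase with a YTH domain, which binds RNA carrying N6-methyladenosine (m6A). The series asked how deleting it in adult mice changes gene expression in pachytene spermatocytes, in 3 iKO and 3 heterozygous libraries. Sums of the deposited normalized counts over genes were 43332241, 38062703 and 42893726 in the heterozygous libraries and 34377384, 35072776 and 34350113 in the iKO libraries. These sums are not sequencing depths, which are unknown. The 100 most abundant genes held 15.8% to 16.3% of the sum in the heterozygous and 14.0% to 14.2% in the iKO libraries. Correlations across genes of log2 values ran from 0.961 to 0.976 within groups and from 0.892 to 0.948 between them, over genes that are not independent replicates. The component with the largest variance, 65.2% of it, separated the groups.

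Ythdc2 itself was lower in every iKO library. Its normalized count was 971, 1222 and 1175 in the heterozygous libraries and 431, 611 and 688 in the iKO libraries. The mean fell from 1123 ± 133 to 577 ± 132 (SD, n = 3 each), which is 51.4% of the heterozygous level, a log2 fold change of -0.98 (SE 0.213, limma adjusted p = 0.0067). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 allows. Ythdc2 (ENSMUSG00000034653.11) lies on chromosome 18 from 44827746 to 44889724 on the + strand of GRCm38. The values count the whole gene and the labels do not name the floxed exons, so they do not measure the share of recombined alleles.

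Meioc, which encodes a meiotic partner protein of YTHDC2, rose 2.82-fold, from 11740 ± 195 to 33640 ± 6995 (SE 0.152 on the log2 scale, limma adjusted p = 0.000798). It lies on chromosome 11 from 102663716 to 102682237. Other genes tied to YTHDC2 did not pass the test with the deposited scaling. Rbm46, a further RNA-binding partner, had a log2 fold change of 0.26 (SE 0.145, adjusted p = 0.185). The exonuclease gene Xrn1 had 0.38 (SE 0.150, adjusted p = 0.0701), and the mitotic cyclin gene Ccna2 had 0.35 (SE 0.366, adjusted p = 0.495). Rbm46 passed with quantile scaling (adjusted p = 0.0204) and Xrn1 with TMM scaling (adjusted p = 0.0455), with array weights (0.012) and without iKO replicate 1 (0.0378), while Ccna2 turned to -0.20 with quantile scaling without passing.

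**Figure D1:**
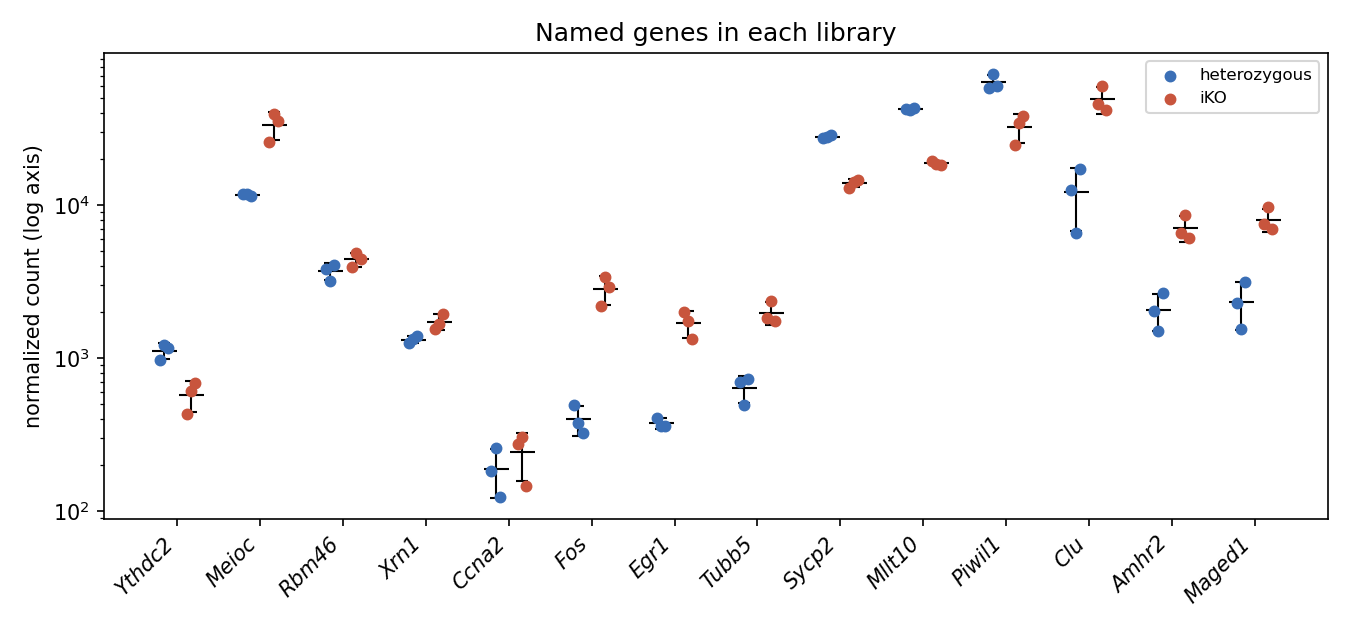
Normalized count on a log axis for 14 named genes, with a point for each library (blue heterozygous, red iKO), a bar for the mean and whiskers of 1 SD, n = 3 per group. Ythdc2 lay between 431 and 688 in the iKO libraries and between 971 and 1222 in the heterozygous libraries, while Rbm46 and Ccna2 overlapped between groups.

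Across the transcriptome 2806 genes rose and 2456 fell in the iKO libraries, 38.3% of the 13750 tested. Fallen genes numbered 1335 without heterozygous replicate 1, 1419 without heterozygous replicate 3 and 1607 without iKO replicate 2. Of genes changed at least 2-fold, 2160 rose and 363 fell. With quantile scaling the at least 2-fold split was 1226 to 757, and that over all called genes 1986 to 2251. Direction followed abundance: among the 3438 genes with the lowest mean over all libraries 1111 rose and 148 fell, and among the 3438 with the highest 134 rose and 1361 fell. The median log2 fold change moved from 0.50 in the lowest of these sets to -0.31 in the highest, and was 0.01 over all genes.

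The largest increases among well-expressed genes included the transcription factor genes Fos (398 ± 87.3 to 2839 ± 614, log2 fold change 2.83, SE 0.221) and Fosb (2.54), and Epas1, which encodes the hypoxia factor HIF-2 alpha (2.80, SE 0.295). Adgra3, an adhesion receptor gene, rose 7.35-fold, the connexin 43 gene Gja1 rose 5.90-fold and the endocytic receptor gene Lrp1 rose 5.66-fold. Creg1 rose by 2.65 and Zfp36, which encodes a protein that promotes decay of AU-rich mRNAs, rose by 2.48. Lrp1 did not pass without iKO replicate 1 or without iKO replicate 2 (adjusted p = 0.0539 in both), and its log2 fold change was smaller, 1.53, without heterozygous replicate 2. Eno1b (2.95) is a near copy of Eno1, and Prn (2.87) overlaps Prnd, so reads may have been divided between these genes. All 10 had limma adjusted p-values between 0.000471 and 0.0153. In the same iKO libraries Sertoli markers were higher, with a median log2 fold change of 2.12.

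The largest decreases were smaller. Mreg, the melanoregulin gene, fell by 2.01 on the log2 scale, from 1433 ± 210 to 353 ± 27.3 (SE 0.181, limma adjusted p = 0.00058). The histone demethylase gene Phf2 fell by 1.75, from 16380 ± 1617 to 4909 ± 813, and the sulfotransferase gene Chst1 fell by 1.70 from 8951 ± 1571. Vps39, a gene of the HOPS tethering complex, fell as well (log2 fold change -1.89), as did Wdr17 (-1.75), the ciliogenesis gene Fuz (-1.71), 1700006A11Rik (-1.65) and the calcium channel gene Ryr3 (-1.61). Vps39 varied widely among the heterozygous libraries (3219 ± 1865). 1700024B05Rik (-1.96) and Gm9732 (-1.68) lie in a part of chromosome 14 with many similar copies, so their reads may have been divided between copies.

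Markers of somatic testis cells were higher in the iKO libraries. All 21 Sertoli markers measured rose, over all genes and when adjusted over the list alone, with a median log2 fold change of 2.12 (camera adjusted p = 2.1e-09; adjusted p = 0.578 with an estimated correlation). Clu rose from 12170 ± 5388 to 49270 ± 9858, the cathepsin gene Ctsl from 4404 ± 1973 to 19440 ± 5539, and Amhr2, the receptor gene for anti-Müllerian hormone, from 2068 ± 573 to 7129 ± 1351. The transferrin gene Trf rose 12.8-fold and Prnd 3.86-fold. Of 11 endothelial markers 9 rose (11 adjusted over the list alone; median 2.27, camera adjusted p = 0.000237; adjusted p = 0.578 with an estimated correlation), among them Cdh5 (VE-cadherin, 5.33-fold), Kdr, Tek and Cldn5. Vwf had 1.15 (adjusted p = 0.0774) and passed with the replicate number as a block (0.0444), with array weights (0.0127) and without iKO replicate 1 (0.012).

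Among 11 peritubular and stromal markers 7 rose (7 adjusted over the list alone; median 1.57, camera adjusted p = 0.00127; adjusted p = 0.578 with an estimated correlation), including Igfbp7, Myl9, Pdgfrb and the collagen gene Col3a1 (7.77-fold). Without iKO replicate 1 the count was 11, and with quantile scaling it was 5, with a median of 0.88. Of 15 Leydig markers 4 rose, Scarb1, Nr5a1, Aldh1a1 and Hsd3b1 (4 adjusted over the list alone; median 1.17, camera adjusted p = 0.00499; adjusted p = 0.631 with an estimated correlation). Without iKO replicate 3 the count was 14 and the median 2.03, while the median was 0.56 without iKO replicate 2 and 0.76 with quantile scaling. The mean log2 level of the Leydig list was 9.09, 10.32 and 8.14 in the iKO libraries and 8.14, 7.36 and 8.11 in the heterozygous ones. Mrc1 and Cd74 rose among 6 macrophage and leukocyte markers (2 adjusted over the list alone; median 0.78, camera adjusted p = 0.133), and Alas2 of 2 red cell markers (2 adjusted over the list alone; median 2.22, camera adjusted p = 0.177). Adgre1, Csf1r and Lyz2 did not pass, nor did Hba-a1 (adjusted p = 0.0686). Adgre1 passed with array weights (0.0338) and without heterozygous replicate 2 (0.0316), Hba-a1 passed without heterozygous replicate 3 (0.0424), and Csf1r, at 0.56, turned to -0.12 with quantile scaling. Without heterozygous replicate 2 the macrophage and leukocyte list passed (camera adjusted p = 0.0453, median 1.24), and with quantile scaling its median was 0.16. Without iKO replicate 2, or with quantile scaling, Cd74 did not pass (adjusted p = 0.0579 and 0.0674).

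**Figure D2:**
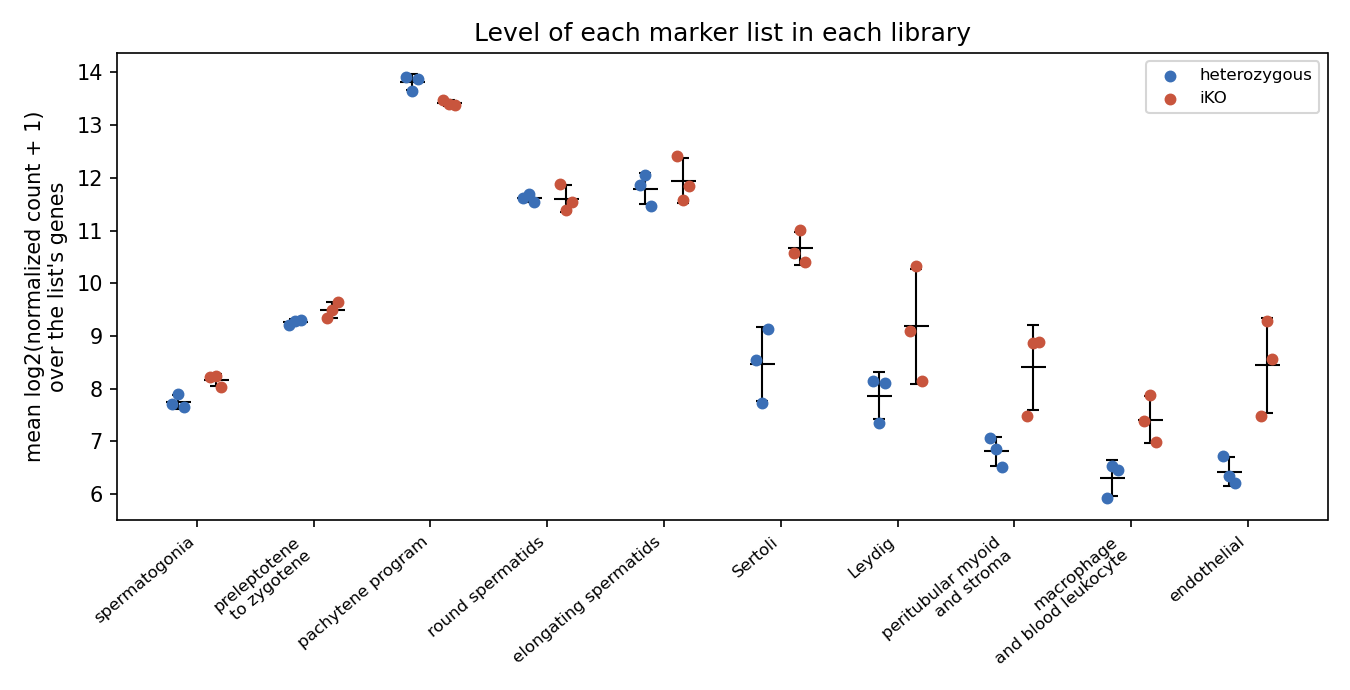
Mean log2(normalized count + 1) over the genes of each marker list and of the pachytene list, with a point for each library (blue heterozygous, red iKO), a bar for the mean and whiskers of 1 SD, n = 3 per group. The Sertoli list lay between 10.40 and 11.02 in the iKO libraries and between 7.73 and 9.13 in the heterozygous libraries, while the spermatid lists overlapped between groups.

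Immediate early genes, which are transcribed within minutes of many stimuli, rose together. Of 21 measured 18 rose (18 adjusted over the list alone), with a median log2 fold change of 2.22 (camera adjusted p = 1.74e-11; adjusted p = 0.0583 with an estimated correlation). Egr1 rose from 376 ± 29.0 to 1701 ± 344 (log2 fold change 2.16, SE 0.196) and Btg2, an antiproliferative gene, from 192 ± 44.3 to 1137 ± 199, besides Fos and Zfp36. The list keeps a median of 1.77 with quantile scaling. Somatic markers were also higher in the iKO group, the Sertoli list having a median of 2.12. Within the heterozygous group the mean log2 level of the Sertoli list ran from 7.73 to 9.13. That of the immediate early list ran only from 7.38 to 7.53.

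Stress lists held members that went both ways. Of 28 DNA damage and apoptosis genes 13 rose and 3 fell (13 and 4 adjusted over the list alone; median 0.65, camera adjusted p = 0.0507; adjusted p = 0.578 with an estimated correlation). The p21 gene Cdkn1a rose 3.22-fold and the stress gene Ddit4 5.02-fold, and the survival gene Bcl2l1 fell by 0.96. This list passed with TMM scaling (camera adjusted p = 0.0488), without heterozygous replicate 1 (0.0236) and without heterozygous replicate 2 (0.0477), and held 8 risen genes without iKO replicate 2. With quantile scaling 8 rose and the median was 0.26 (0.255). Of 26 heat shock and unfolded protein response genes 9 rose and 3 fell (11 and 5 adjusted over the list alone; median 0.07, camera adjusted p = 0.357), with Hspb1, the mitochondrial chaperonin gene Hspd1, Atf3 and Sesn2 higher. With quantile scaling this list passed (camera adjusted p = 0.00574), with a median of 0.27. Without heterozygous replicate 2 its median was -0.04 and 6 fell, without heterozygous replicate 3 the median was 0.23 and 1 fell, and without iKO replicate 1 or 3 the median was 0.17 or 0.11. Of 10 interferon response genes 6 rose and 2 fell, the same counts adjusted over the list alone (median 1.08, camera adjusted p = 0.104), and with quantile scaling 2 rose and 3 fell, with a median of 0.62. With any 1 library left out 1 gene fell. Oasl2, Irf1, Irf9 and Ifih1 rose, and 3 genes of this list rose without iKO replicate 2 and 4 without iKO replicate 3. Irf9 and Ifih1 did not pass with quantile scaling (adjusted p = 0.111 and 0.122), nor Ifih1 without iKO replicate 2. Sertoli markers (median 2.12) were higher in the same libraries.

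X-linked genes, most of which are silenced in pachytene spermatocytes, were called higher more often than autosomal ones. Of 503 tested 241 rose, 47.9%, against 16.1% to 24.0% on single autosomes (251 rose and 1 fell adjusted over the list alone). Their median log2 fold change was 0.89 (camera adjusted p = 7.77e-15; adjusted p = 0.578 with an estimated correlation). Maged1 rose from 2343 ± 811 to 8070 ± 1407, the chromatin gene Rbbp7 from 501 ± 44.8 to 1672 ± 456, Cited1 from 201 ± 79.3 to 1035 ± 158 and Pcyt1b from 34.7 ± 12.1 to 321 ± 116. Autosomal genes matched on mean level rose in 31.8% of cases, with a median of 0.37. Quantile scaling gave 153 risen and 6 fallen X-linked genes with a median of 0.36, on a scale where the median over all genes was -0.07. Among 19 X-linked genes restricted to germ cells, Mageb16 and Ott rose, both chosen after their values were seen, and the median was 0.13. Ott (log2 fold change 6.08 in limma) was listed at 0 in heterozygous replicates 1 and 2, and did not pass in the authors' DESeq2 comparison (log2 fold change 0.12, adjusted p = 0.267). Its group means were 21.8 and 291, so the authors' fold change is not a plain ratio of means. The Leydig, stromal, Sertoli and endothelial marker lists had medians from 1.17 (Leydig; 0.56 without iKO replicate 2) to 2.27 (endothelial) in the same libraries.

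Few Y-linked genes passed the test. Of 67 measured 3 rose and 1 fell (1 rose adjusted over the list alone), with a median of 0.01 (camera adjusted p = 0.949) that was -0.42 with quantile scaling (camera adjusted p = 0.0109) and -0.10 without iKO replicate 1. With another library left out it lay between -0.003 (without heterozygous replicate 1) and 0.13 (0.125, without iKO replicate 3). Ddx3y, a widely expressed RNA helicase gene, rose 3.01-fold and Eif2s3y 1.51-fold. Eif2s3y did not pass with the replicate number as a block (adjusted p = 0.0596), with quantile scaling (0.169), or without heterozygous replicate 1 (0.138) or 3 (0.101), or iKO replicate 1 (0.0757) or 2 (0.0831). Gm20896 and Gm20869 are members of a multicopy family with libraries listed at 0, and their opposite calls may come from reads divided between copies. Neither passed with quantile scaling, in limma without trend, or without heterozygous replicate 1, heterozygous replicate 2, iKO replicate 1 or iKO replicate 3. Gm20896 did not pass with array weights either, nor Gm20869 with TMM scaling or without heterozygous replicate 3.

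**Figure D3:**
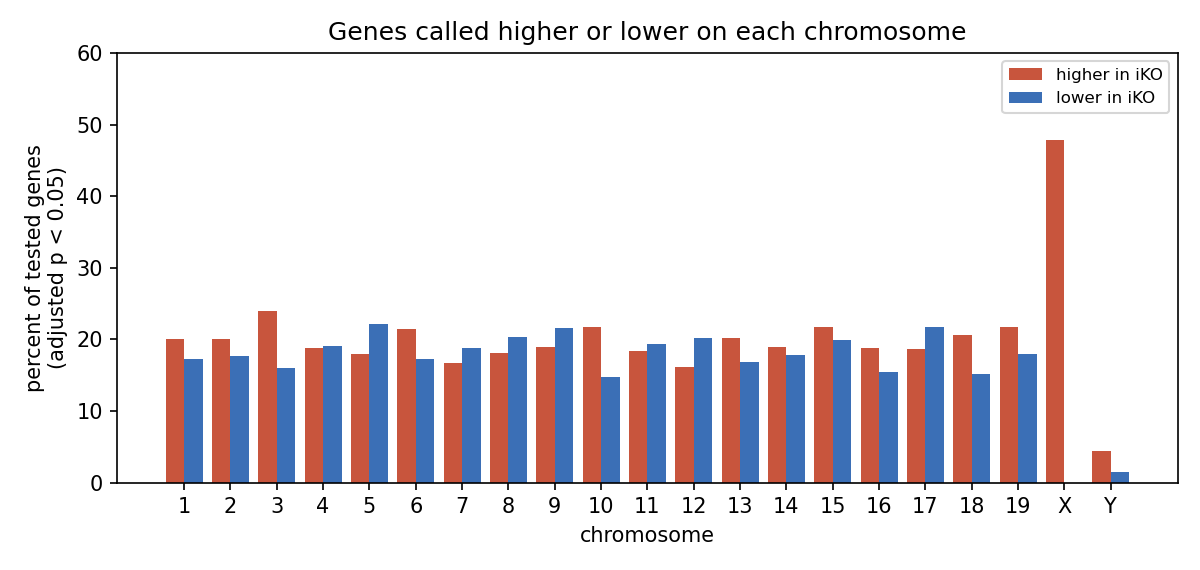
Percent of tested genes called higher (red) or lower (blue) in iKO on each chromosome, limma adjusted p under 0.05. Chromosome X stands at 47.9% higher, against at most 24.0% on an autosome.

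Genes of the pachytene program, expressed at high levels at this stage, were lower. Of 35 measured 19 fell and the other 16 did not pass (21 fell and 1 rose adjusted over the list alone), with a median log2 fold change of -0.42 (camera adjusted p = 9.34e-05; adjusted p = 0.578 with an estimated correlation). Mllt10 fell from 42600 ± 727 to 18770 ± 541, the transcription factor gene Tcfl5 from 22140 ± 2277 to 12610 ± 121, Ybx3 from 87770 ± 3521 to 58070 ± 3068, and Piwil1, which encodes a piRNA-binding protein, from 63620 ± 7241 to 32560 ± 6857. Random lists matched on mean level had a median of -0.39, and 34% of them lay below this list. With quantile scaling 5 fell and 2 rose (median -0.02, camera adjusted p = 0.635), and Ybx3 (adjusted p = 0.368) and Piwil1 (0.05 after rounding) did not pass. The count of fallen genes was 10 without heterozygous replicate 1, 11 without heterozygous replicate 3, 12 without iKO replicate 2 and 11 without iKO replicate 3.

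Of 21 piRNA pathway genes 12 fell and 1 rose (13 and 1 adjusted over the list alone; median -0.39, camera adjusted p = 0.00121; adjusted p = 0.578 with an estimated correlation). Besides Piwil1, the mitochondrial factor Pld6 fell by 1.16 on the log2 scale, the piRNA methyltransferase gene Henmt1 fell by 0.87 and Tdrd3 fell by 0.64. Of matched random lists 24.7% lay below this one. Quantile scaling gave 3 fallen and 1 risen (median -0.10, camera adjusted p = 0.378), and 6, 7 and 6 genes fell without heterozygous replicate 1, heterozygous replicate 3 and iKO replicate 2. Sertoli markers (median 2.12) were higher in the iKO group, where the pachytene and piRNA lists were lower. Within the heterozygous group this varied. Replicate 2 had the lowest pachytene level (13.64) and also the lowest Sertoli level (7.73). Replicate 3 had the lowest piRNA level (12.90) and the highest Sertoli level (9.13).

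The structural meiotic lists did not pass camera with the deposited scaling, and no test compared them with the pachytene or piRNA list. Of 12 synaptonemal complex genes 2 fell and 2 rose, the same counts adjusted over the list alone (median -0.12, 0.02 with quantile scaling, 0.12 without iKO replicate 1, and -0.06, -0.18 and -0.23 without heterozygous replicate 2, iKO replicate 2 and iKO replicate 3; camera adjusted p = 0.596). Sycp2, which encodes an axial element protein, fell from 28090 ± 701 to 13970 ± 899 (log2 fold change -1.01, SE 0.102, limma adjusted p = 0.000798), Syce1 fell by 0.42, and Hormad2 rose by 0.79 and Fkbp6 by 0.78. The calls of Syce1, Hormad2 and Fkbp6 were lost with quantile scaling, where Syce1 turned to 0.02, and without heterozygous replicate 1, heterozygous replicate 3, iKO replicate 2 or iKO replicate 3. Syce1 was also lost without iKO replicate 1 (adjusted p = 0.0776), and Fkbp6 without heterozygous replicate 2 (0.0544), and neither passed in limma without trend.

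Of 27 recombination genes 4 fell, also adjusted over the list alone (median -0.07, 0.03 without heterozygous replicate 2, -0.16 (-0.155) without heterozygous replicate 1, -0.01 without iKO replicate 1, and -0.20 without iKO replicate 3 and with quantile scaling; camera adjusted p = 0.396). They were Ccdc36, Ankrd31 and Spo11, which act in the formation of meiotic DNA breaks, and Psmc3ip, an accessory factor of strand exchange. Ccdc36 fell from 2050 ± 254 to 830 ± 102, while Spo11 (-0.63) did not pass with quantile scaling (adjusted p = 0.0755). Among 16 cohesin and telomere attachment genes 5 fell and 1 rose, likewise adjusted over the list alone (median -0.40, and -0.32 (-0.315) with quantile scaling; camera adjusted p = 0.104), and 3.24% of matched random lists lay below this list. The meiotic cohesin gene Stag3 fell from 31100 ± 2988 to 19290 ± 1180, with Cdk2 and Terb1, and the cohesin gene Rec8 rose by 0.56. Fallen genes of this list numbered 2 without heterozygous replicate 1 or 3 and 3 without iKO replicate 2 or 3 and with the replicate number as a block. Terb1 did not pass without heterozygous replicate 1, heterozygous replicate 3 or iKO replicate 3, nor Rec8 without heterozygous replicate 3 or iKO replicate 3. The Sertoli list (median 2.12) was higher in these libraries too.

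**Figure D4:**
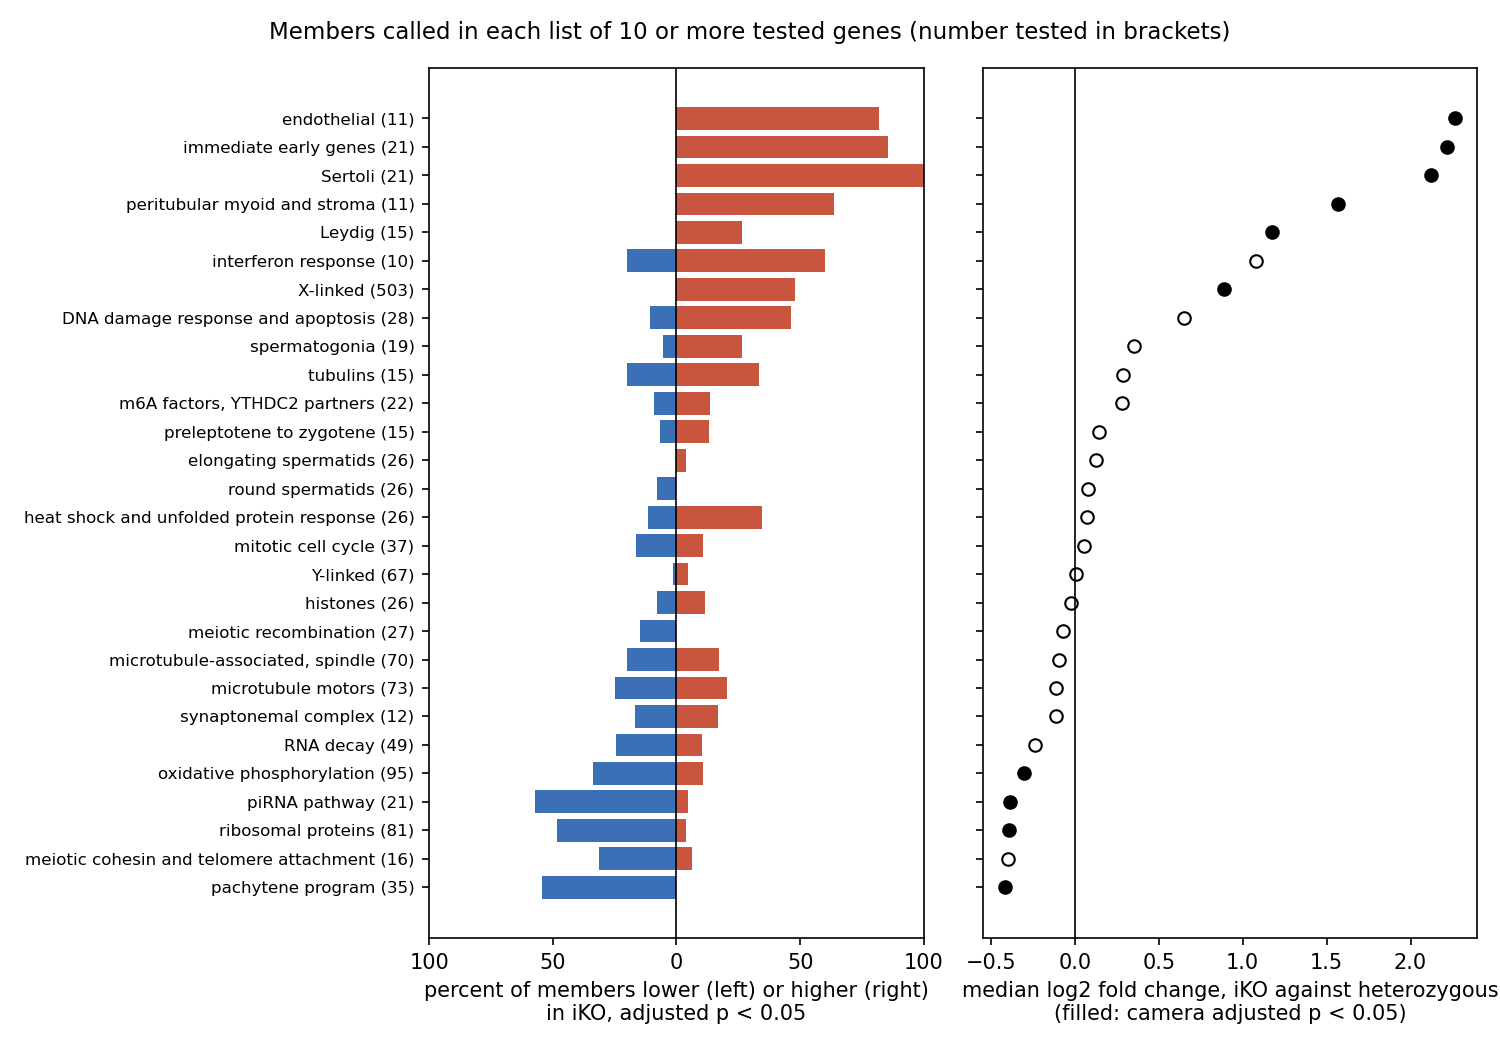
Left, percent of each list's tested genes called lower (blue, left of 0) or higher (red, right of 0) in iKO by limma. Right, each list's median log2 fold change, filled where the camera adjusted p was under 0.05 with the preset correlation, from -0.42 for the pachytene program to 2.27 for the endothelial markers. Lists with at least 10 tested genes are shown.

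Ribosomal protein genes called lower and those called higher lay on different chromosomes. Of 81 tested 39 fell and 3 rose (43 and 4 adjusted over the list alone; median -0.39, camera adjusted p = 1.05e-06; adjusted p = 0.578 with an estimated correlation). All 39 were among the 77 autosomal genes, and the 3 that rose, Rpl10, Rps4x and Rpl39, chosen after their values were seen, were among the 4 X-linked genes. These 3 were low, with heterozygous means of 405, 181 and 114. Since direction followed abundance over all genes, chromosome cannot be told from level here. Rpl31 fell from 7804 ± 355 to 4688 ± 339 and Rps27 from 6840 ± 443 to 4210 ± 162, with Rpl24 and Rps25. Of matched random lists 0.31% lay below the median of this list, but these did not keep the correlation between its members, estimated at 0.393. With quantile scaling 10 fell and 4 rose (median -0.15, camera adjusted p = 0.146), and 17, 17 and 25 fell without heterozygous replicate 1, heterozygous replicate 3 and iKO replicate 2.

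Of 95 oxidative phosphorylation genes 32 fell and 10 rose (33 and 10 adjusted over the list alone; median -0.30, camera adjusted p = 0.000713; adjusted p = 0.578 with an estimated correlation). Cox7b2, a cytochrome oxidase subunit gene, fell from 7902 ± 1383 to 4428 ± 134. In contrast Cycs, which encodes somatic cytochrome c, rose 3.75-fold and Atp5g2 2.62-fold. Of 13 genes of the mitochondrial genome 5 rose and 1 fell, with mt-Nd1 at 30410 ± 4944 and 55960 ± 5472, while 31 of 82 nuclear genes fell and 5 rose. Of matched random lists 2.73% lay below this list. With quantile scaling the list did not pass (median -0.13, camera adjusted p = 0.209), and 16, 16 and 19 genes fell without heterozygous replicate 1, heterozygous replicate 3 and iKO replicate 2. Sertoli markers (median 2.12) were higher in the iKO group, in which the ribosomal and respiratory lists were lower.

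Tubulin genes moved both ways. Of 15 measured 5 rose and 3 fell, the same adjusted over the list alone (median 0.29, camera adjusted p = 0.318). The median was 0.13 without heterozygous replicate 3, 0.12 without iKO replicate 1 and 0.15 with quantile scaling. The widely expressed genes Tuba1a (929 ± 414 to 3496 ± 547), Tuba1b, Tubb3 and Tubb5 rose between 2.28-fold and 4.03-fold. The abundant testis genes Tuba3a and Tuba3b, chosen after their values were seen, fell by 0.45 and fell by 0.53, and as near copies they may share reads. With quantile scaling Tuba3a had 0.05 and neither passed, and Tuba3a did not pass in limma without trend (adjusted p = 0.0547). Of 73 motor genes 15 rose and 18 fell (15 and 19 adjusted over the list alone; median -0.11, mean 0.06, and median 0.02 with quantile scaling; camera adjusted p = 0.461). The kinesin genes Kif24, Kif6 and Kif15 fell, and the dynein gene Dync1i1 rose 2.68-fold. Of 70 microtubule-associated and spindle genes 12 rose and 14 fell, likewise adjusted over the list alone (median -0.10, mean 0.11, and median 0.02 with quantile scaling; camera adjusted p = 0.461). Tacc2 rose 4.36-fold and the kinase gene Mark4 2.67-fold, while its relative Mark2 fell by 1.35 and Fignl1 fell by 0.87. With quantile scaling 12 motor genes rose and 9 fell, and 13 spindle genes rose and 8 fell. Fallen motor genes numbered 9, 8 and 8 without heterozygous replicate 1, heterozygous replicate 3 and iKO replicate 3, and risen ones 9 and 8 without iKO replicate 2 and iKO replicate 3. The motor median was -0.07 without heterozygous replicate 1 or iKO replicate 3, and the spindle median -0.05 without iKO replicate 1. Fallen spindle genes numbered 6, 8 and 9 without heterozygous replicate 1, heterozygous replicate 3 and iKO replicate 2, where 7 rose.

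Of 37 mitotic cell cycle genes 4 rose and 6 fell, also adjusted over the list alone (median 0.05, camera adjusted p = 0.95). The cyclin kinase inhibitor genes moved apart: Cdkn1a and Cdkn1b rose 3.22-fold and 3.81-fold, Cdkn2c fell from 7228 ± 1369 to 3806 ± 210, and Cdc20 fell by 0.64. Without heterozygous replicate 2 the counts were 7 and 10, and with 1 library left out the median ran from -0.03 (-0.025, without iKO replicate 2) to 0.24 (without iKO replicate 3). Of 22 m6A factors and YTHDC2 partners 3 rose and 2 fell (2 and 1 adjusted over the list alone; median 0.28, 0.16 with quantile scaling; camera adjusted p = 0.446). Besides Meioc, Fmr1 rose by 1.13, and the nuclear reader gene Ythdc1 fell by 0.74 and the methyltransferase gene Mettl16 fell by 0.50. Fmr1 did not pass with quantile scaling (adjusted p = 0.130), without heterozygous replicate 1, or without iKO replicate 1 or 2, and Mettl16 did not pass with the replicate number as a block (adjusted p = 0.0683), without heterozygous replicate 1 or 3, or without iKO replicate 2 or 3. In this list 1 gene rose without heterozygous replicate 1 or iKO replicate 2, and 5 rose without heterozygous replicate 2 or iKO replicate 1.

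Of 49 RNA decay genes 12 fell and 5 rose, also adjusted over the list alone (median -0.24, camera adjusted p = 0.0967). Upf1, the helicase of nonsense-mediated decay, fell from 9464 ± 425 to 5498 ± 629 and the exonuclease gene Dis3l fell by 0.66, while Zfp36 and the exosome gene Exosc8 rose. Fallen genes numbered 6 without heterozygous replicate 1 or 3 and 7 without iKO replicate 2 or 3 and with quantile scaling, where the median was -0.11. Of 26 histone genes 3 rose and 2 fell (2 and 2 adjusted over the list alone; median -0.03, mean 0.11, camera adjusted p = 0.84). Hist2h2be fell by 1.20 and H2afz fell by 0.70, and the low genes Hist1h1c and Hist1h2bc rose. The histone median was 0.05 (0.045) without heterozygous replicate 2, 0.10 without iKO replicate 2, -0.09 without iKO replicate 3, -0.07 without heterozygous replicate 3, -0.04 without heterozygous replicate 1 and -0.35 with quantile scaling, and H2afz did not pass with quantile scaling (adjusted p = 0.0565). Sertoli markers (median 2.12) were higher in the same iKO libraries as these tubulin, cell cycle, decay and histone genes.

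Lists of markers of other germ cell stages had lower medians than those of somatic markers, except that with quantile scaling the elongating spermatid median, 0.25, exceeded that of the macrophage and leukocyte list, 0.16. Of 19 spermatogonial markers 5 rose and 1 fell, also adjusted over the list alone (median 0.35, and -0.12 with quantile scaling, where 2 rose and 2 fell; camera adjusted p = 0.213). Uchl1 rose 2.43-fold and Prss50 1.99-fold, and Dmrtb1 fell by 0.56. Etv5, a transcription factor gene of this list, rose 4.46-fold (2.16 on the log2 scale), near the Sertoli median of 2.12. Which cells its signal came from was not tested. Prss50 and Dmrtb1 did not pass with quantile scaling (adjusted p = 0.146 and 0.208), nor Uchl1 without heterozygous replicate 2 or 3 or iKO replicate 2. Risen spermatogonial markers numbered 3 without heterozygous replicate 1 or 3, and 2 without iKO replicate 2. The median was 0.17 without heterozygous replicate 1 and 0.53 without heterozygous replicate 2. Among 15 markers of preleptotene to zygotene spermatocytes Gm4969 and Rec8 rose and Spo11 fell (2 and 1 adjusted over the list alone; median 0.14, camera adjusted p = 0.451), while the meiotic entry gene Stra8 had 0.74 (adjusted p = 0.0518; 0.0419 with TMM scaling, 0.0385 without trend, 0.0106 with array weights and 0.0201 without iKO replicate 1). The median of this list was 0.37 without heterozygous replicate 2, 0.22 without heterozygous replicate 3 and 0.09 without iKO replicate 3. Its risen genes numbered 4 without iKO replicate 1, where 2 fell, 1 without heterozygous replicate 3 or iKO replicate 2, and 0 without iKO replicate 3. Gm4969 did not pass with quantile scaling (adjusted p = 0.334) or without heterozygous replicate 1 or iKO replicate 2 or 3. Sertoli markers (median 2.12) were higher in these libraries as well.

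Of 26 round spermatid markers Dkkl1 and 1700029P11Rik fell, also adjusted over the list alone (median 0.08, mean -0.01, camera adjusted p = 0.809), and Dkkl1 did not pass with quantile scaling (adjusted p = 0.486) or without iKO replicate 2 (0.0541). The median turned to -0.09 without iKO replicate 1, and was 0.02 without heterozygous replicate 3, 0.14 without iKO replicate 3, 0.17 without heterozygous replicate 2 and 0.20 without iKO replicate 2. With quantile scaling 2 rose and 1 fell. Fallen round spermatid markers numbered 4 without heterozygous replicate 2 and 1 without iKO replicate 2. Of 26 elongating spermatid markers Smcp rose by 0.51 (adjusted p = 0.0455; 0.317 adjusted over the list alone; median 0.13, camera adjusted p = 0.497). Smcp did not pass with TMM scaling (adjusted p = 0.0564), in limma without trend (0.110), or when any library but heterozygous replicate 2 was left out, and the list passed with quantile scaling (camera adjusted p = 0.0432). The elongating median turned to -0.11 without iKO replicate 1 and -0.05 without heterozygous replicate 3, and was 0.26 without heterozygous replicate 2 and 0.33 without iKO replicate 2. The protamine gene Prm2 (10980 ± 4190 and 13450 ± 4884) and the sperm tail gene Odf1 (6730 ± 1397 and 9169 ± 1290) did not pass with the deposited scaling. Odf1 passed with quantile scaling (adjusted p = 0.0207), with array weights (0.0158) and without heterozygous replicate 2 (0.0197), and Prm2, at 0.32, turned to -0.05 (-0.045) without heterozygous replicate 3. Sertoli markers (median 2.12) were higher in these libraries too.

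The authors' deposited table gives an adjusted p under 0.05 for 5493 genes, 3047 higher and 2446 lower in iKO. Of these, 5103 were also called by limma, all in the same direction. Limma called a further 159 genes that had no adjusted p under 0.05 there, Ott among them. The authors' deposited lists of changed genes use other thresholds, since their adjusted p reaches 0.1 and their log2 fold changes start at 0.501 and -0.5. They hold 3147 higher and 1812 lower genes, and limma called 86.2% and 92.7% of them in that direction. In the authors' deposited table Ythdc2 and Meioc had log2 fold changes of -0.90 and 1.47.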

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

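The counts of called genes (5262, and 2523 at least 2-fold) stayed within 1.5 times of these values under each other scaling, filter, pseudocount and test, over 4237 to 7273 and 1983 to 2900 genes, and over 3543 to 5528 and 2005 to 2633 when 1 library was left out. Fallen genes taken alone (2456) moved further, to 1335 without heterozygous replicate 1, 1419 without heterozygous replicate 3 and 1607 without iKO replicate 2. The at least 2-fold genes taken by direction moved further with quantile scaling, from 2160 higher and 363 lower to 1226 and 757. With quantile scaling 4237 genes were called, 3277 of them also called without it. Ythdc2 stayed lower and past the threshold in each of these fits, with log2 fold changes from -0.78 to -1.17. The replicate numbers of the titles do not pair the libraries: same-numbered libraries had correlations of deviations of 0.024, -0.138 and -0.092, and 0 libraries correlated best with their own number. With the replicate number as a block, 4845 genes were called and 2498 at least 2-fold, and 10 lists. The number of lists passing camera was 10, between 9 and 11 under other scalings, filters and tests, between 10 and 12 with 1 library left out, and 0 with an estimated correlation. Adding the Sertoli marker level as a covariate, chosen after seeing the data, left 0 genes called by limma and 0 at least 2-fold, with 2725 genes at an unadjusted p under 0.05. That covariate shares 85.8% of its variance with the groups, so it removes most of the comparison by construction. The Leydig marker level, which shares 48.3%, left 1457 genes and 1003 at least 2-fold. Without X-linked genes 5029 and 2301 were called. With quantile scaling Syce1 reversed to 0.023 and Tuba3a to 0.054, and the cause was not tested. Leaving out heterozygous replicate 1 or 3 raised the share of called genes that were higher from 53.3% to 62.5% and 62.0%. Without heterozygous replicate 2 that share was 47.3%, with 2615 genes higher and 2913 lower. Quantile scaling moved the median of all genes to -0.07 and ended the camera calls of the pachytene, piRNA, ribosomal and oxidative phosphorylation lists. Depth is unknown, so counting error could not be separated from the spread between animals.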

Other observations

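Some families of genes sharing a symbol stem held a larger share of genes called in 1 direction than other genes did, in a search over 92 families of at least 15 genes. The search included members of the fixed lists and was made after the data were seen. For lower genes 5 families passed: Cfap, Dnah, Ccdc, and Rpl and Rps, which largely repeat the ribosomal list (47 of 48 and 30 of 41 members). Of random lists of like mean level, 0.9% had a median below that of Rpl and 23.1% below that of Rps. For higher genes 4 passed: Slc, Sema, Klf and Aldh. Of the genes of cilia and flagella proteins 21 of 31 Cfap genes fell (one-sided Fisher's exact test on genes, adjusted p = 1.17e-07), with a median log2 fold change of -0.62, and 14 fell with quantile scaling (median -0.40). Cfap70 fell from 25540 ± 3285 to 12240 ± 1063 (SD, n = 3 each; limma adjusted p = 0.00121). Of 15 Dnah genes, which encode axonemal dynein heavy chains, 11 fell (adjusted p = 0.000119, median -0.63), and 5 fell with quantile scaling (median -0.26). Dnah17 fell from 75700 ± 3122 to 42960 ± 1962. For both families 0% of 1000 random lists of like mean level had a lower median. With any 1 library left out, 17 to 23 Cfap genes and 9 to 11 Dnah genes fell. These families fell in the same iKO libraries in which Sertoli markers rose, with a median of 2.12. Of 122 Ccdc genes, which share a coiled-coil domain name, 36 fell and 10 rose (adjusted p = 0.0211, median -0.16), with 25.4% of random lists lower. Genes are not independent replicates in these tests.

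Among the families that passed for higher genes, 79 of 237 solute carrier (Slc) genes rose and 23 fell (adjusted p = 0.000172, median 0.38, and 0.15 with quantile scaling, where 61 rose and 26 fell). Fallen Slc genes numbered 14 without heterozygous replicate 1 or 3 and 15 without iKO replicate 2 or 3. Of 15 semaphorin genes 11 rose (one-sided Fisher's exact test on genes, adjusted p = 0.000694, median 1.18), and 7 rose and 1 fell with quantile scaling (median 0.56). Without heterozygous replicate 3 or without iKO replicate 2, 7 rose. Sema7a rose from 659 ± 218 to 3007 ± 552. Of 15 Klf transcription factor genes, 3 of them in the immediate early list, 9 rose (adjusted p = 0.0279, median 0.87, and 0.53 without iKO replicate 1), and 5 rose with quantile scaling (median 0.52). Of random lists of like mean level, 90% lay below the Klf median, against 99.7% for the semaphorin genes and 100% for Slc and Aldh. Of 19 aldehyde dehydrogenase genes 10 rose and 1 fell (adjusted p = 0.0424, median 1.09, and 0.44 with quantile scaling), among them Aldh7a1, from 523 ± 165 to 2243 ± 657. Aldh1a1, also in the Leydig list, is a member, and of the other 18 genes 9 rose. These families rose in the same libraries as the Sertoli markers, whose median was 2.12.

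Since direction followed abundance, list medians were also set among random lists of like mean level, chosen after the data were seen. The round and elongating spermatid lists, with medians of 0.08 and 0.13, lay above 99.8% and 100% of such lists, whose medians were -0.22 and -0.24. Without iKO replicate 1 both spermatid medians turned negative (-0.09 and -0.11), as did that of the elongating list without heterozygous replicate 3 (-0.05), and the random lists were not drawn again for these fits. The lists of m6A factors and YTHDC2 partners (99.6%), DNA damage (99.8%), heat shock (99.0%), tubulins (98.5%), Leydig (99.4%) and stromal markers (99.8%) also lay high. The Sertoli, endothelial, immediate early and X-linked lists lay above 100% of theirs. The Y-linked list lay above 0.04% and the ribosomal list above 0.31%. The other lists lay between 2.73% (oxidative phosphorylation) and 95.6% (red blood cell). Random lists were drawn by level alone, while members of a list can move together. The estimated correlation was 0.885 for the Sertoli, 0.89 for the elongating spermatid and 0.393 for the ribosomal list. These shares are therefore not p-values and can look too extreme.

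Of the tests in the next paragraphs, those of a lower pachytene share, of somatic cells as the source of all X-linked genes or of the immediate early genes, of weaker silencing of the X chromosome, and of a stress response were chosen only after the result was seen, as were the differences taken over libraries. Splitting the 6 libraries into 3 and 3 in all 10 ways, only 1 split, that of the genotypes, gave as many called genes (5262), genes at least 2-fold changed (2523) or X-linked genes risen (241), and the highest other split gave 1 for each. With 10 splits the share cannot go under 0.1.

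Markers of somatic testis cells were higher in the iKO libraries. Whether a smaller share of pachytene cells raised every other cell type alike is not decided. Sertoli markers exceeded round and elongating spermatid markers by a median of 2.01 (2.007, SE 0.054 over genes). Over libraries the gap between their mean levels rose by 2.12 (2.118, SE 0.608). That gap would argue against it only if pachytene cells did not express the spermatid markers. These were abundant in the heterozygous fraction (Dkkl1 at 38370 and Prm2 at 10980), and 1 round spermatid marker is in another list. The authors' scaling is argued against, since the Sertoli median was at least 1.97 with TMM and quantile scaling. Sertoli cells or their RNA in the iKO fraction may be a source: all 10 of the most abundant markers rose (Clu to 49270 normalized counts and Ctsl to 19440), and the SD of the markers' log2 fold changes, 0.382, was undercut by only 0.08% of 10000 random sets of risen genes of like level. Of these 21 markers, 18 had a heterozygous mean above 100 and 0 were in another list, and the Staput separation should remove most Sertoli cells. The test does not separate Sertoli cells from a germ cell change that raises their genes in 1 ratio, and an effect of the deletion on the separation or the tissue stays open as untested.

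X-linked genes were higher in the iKO libraries. GC content or gene length bias is argued against over genes only. X-linked genes exceeded autosomal genes matched on mean level, GC content and transcript length by a median of 0.71 (SE 0.097 over genes). These matches had a median of 0.18, against 0.37 for matches on mean level alone and 0.53 on heterozygous level. The size of the excess thus depends on the matching. Over libraries the gap between the mean levels of X-linked genes and the matches on level, GC content and length rose by 0.62 (0.617, SE 0.163). That is less certain than the SE over genes makes it look, since 0.4, the bound set before, lies within 2 SE. The authors' scaling is argued against too, since 153 rose and 6 fell with quantile scaling. Somatic cells could not be excluded: the X-linked median lay below the highest somatic marker median (endothelial), with a difference of -1.37 (SE 0.261 over genes; -1.06 and SE 0.579 over libraries), although 47.9% rose against 38.4% of autosomal genes matched on heterozygous level. In the part restricted to germ cells the median was 0.13 (0.125, SE 0.103 over genes), which leaves somatic cells open. Its difference from that of autosomal spermatogonial markers, -0.23 (-0.225, SE 0.309 over genes; 0.145 and SE 0.156 for mean levels over libraries), decides nothing about early germ cells, since these genes did not rise beyond their spread. Weaker silencing that raises all X-linked genes alike is argued against only as the sole cause of the rise. The median of the germ cell genes was below that of the other X-linked genes (0.95), with a difference of -0.83 (-0.827, SE 0.138 over genes, and -0.42 and SE 0.138 for mean levels over libraries). If somatic RNA raised the other genes, a smaller rise of all X-linked genes could leave the same gap and stays open. The 4 Y-linked germ cell genes had a median of 0.16, and 0 passed in limma or had an unadjusted p under 0.05. Weaker silencing of part of the X-linked genes after loss of Ythdc2 was not tested and stays open.

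Immediate early genes were higher in the iKO libraries. The gap between their mean log2 level and that of Sertoli markers changed by -0.29 (SE 0.411 over libraries) between groups, too uncertain to tell whether somatic cells are the source. Within groups the immediate early level followed neither the Sertoli nor the endothelial level closely. It ran from 7.38 to 7.53 in the heterozygous libraries, where the Sertoli level ran from 7.73 to 9.13. In the iKO libraries it ran from 9.30 to 9.43 and the endothelial level from 7.48 to 9.28. There iKO replicate 2 was highest in each of these lists. Though not tested, this argues against Sertoli or endothelial cells as the only source. A stress response to cell preparation cannot be told from the deletion either: of 5 heat-inducible genes 3 rose (Hspb1, Hspa1b and Hspa1a), while Hsph1 fell by 0.91 and Dnajb1 did not pass. Somatic cells as part of the source, a stress response and a response of the spermatocytes to the deletion stay open. Preparation and genotype were not crossed. An effect of the recombinase, which goes with the genotype, cannot be told from the deletion either.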
